A study of Homo sapiens and Homo sapiens
Mus musculus with 11 samples.

How the data were processed

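Single-cell RNA sequencing with droplet capture (10x Genomics, as the series title states) was used on adult human testis cells. The series held 11 libraries. The 10 human libraries formed 4 groups. Sorted spermatogonia were given as replicates 1, 2 and 5, steady-state spermatogenic cells as replicates 3, 4 and 5, Sta-Put enriched spermatocytes as replicates 6 and 11, and Sta-Put enriched spermatids as replicates 6 and 11. Sta-Put is sedimentation at unit gravity through an albumin gradient, which separates germ cells by size. One further library held human and mouse cells mixed 1:1 to measure how often a barcode holds more than 1 cell. Tissue was digested enzymatically, and the spermatogonial sort took cells negative for HLA-ABC and CD49e, dim for THY1 and EpCAM and positive for ITGA6, per the labels. The labels give a number to each replicate and do not say whether a number marks a person, a day or a run. The p-values below therefore measure the spread between these libraries. Except with a replicate block, the tests take libraries as independent, although numbers 5, 6 and 11 each occur in more than 1 group.

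The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, as whole numbers without normalization within a library. Cell Ranger and bcl2fastq are named in the submitters' processing notes without versions or settings, and the builds hg19, mm10, GRCh38 and GRCm38 are named there without a role. Whether the counting used strand was not stated, so antisense genes are uncertain. The mixture was deposited as 1 count matrix for human and 1 for mouse genes. Pooled matrices of the 4 groups held 92.96% to 99.43% of the summed UMIs of their libraries and were not used. No pair of libraries of a group was a copy of the other in a check of their gene counts. The libraries analysed here held 32727 barcodes, where the series states 36451 cells. Of 33694 gene identifiers, 33132 matched GENCODE 29, from which chromosomes and positions were taken, and the rest were used without a position.

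Depth per human library ranged from 29846453 to 90288168 UMIs. A count of 0 in a library therefore allows a level of up to 0.0332 to 0.101 CPM (UMI counts scaled to library size), taking 3 counts as the limit. These limits and all binomial intervals cover counting error only.

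For comparisons of whole libraries, UMI counts were summed over all deposited barcodes of each library. The 10 human libraries were fitted together with 4 group means in edgeR 4.0.16 (R 4.3.3) with trimmed-mean (TMM) scaling, the filterByExpr filter and the quasi-likelihood test, so that groups of 2 shared their estimate of spread with groups of 3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were the fold change divided by the root of the F statistic. CPM are means over libraries from edgeR with TMM scaling, and CPM of the mixture and of the libraries set beside it use plain library totals.

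For comparisons within cell classes, barcodes with at least 500 genes and at most 25% mitochondrial UMIs were kept. That removed 74 of 30556 barcodes and left 30482. Counts were scaled to 10000 per cell and log-transformed. Genes with a UMI in 20 or more cells were considered, the 2000 most variable were taken across libraries (scanpy 1.11.5), and 30 principal components and 15 neighbours per cell gave a shared-neighbour graph, which was partitioned with leidenalg 0.10.2 at resolution 0.4 and seed 1. Of the 12 marker lists written before the data were examined, those with at least 5 markers at 50 CPM or more in some cluster were scored in each of the 21 clusters. A cluster took the class of its best list when that score was 1.5 times the next class or more and its 10 leading genes did not hold more markers of another class. The leading genes had at least 50 CPM and were ranked by their fold over the other cells of the same libraries after adding 5 CPM. Small clusters far below their libraries' depth with no leading marker were left unnamed. A first form of this rule asked for 3 markers and 20 CPM. It was changed after its names in the alternative clusterings had been seen, and gave the same names in the main clustering. Scrublet, run per library with an expected rate of 1%, predicted 420 doublets, 1.38% of the kept barcodes. They were kept in the main results and removed in an alternative.

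Class shares were compared by an exact two-sided permutation test of the difference in mean share over libraries. Within a class, counts were summed per library with at least 50 such cells and tested in edgeR as above on the libraries of the groups compared. The share of X-linked UMIs of spermatocyte-like or spermatid-like cells was set against spermatogonia-like cells of the same library, and the log2 ratios were tested by exact two-sided sign flips. Multiplet rates are given with exact binomial 95% intervals.

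The 17 gene lists fixed before the data were examined covered undifferentiated and differentiating spermatogonia, the mitotic cell cycle, synapsis and recombination, meiotic division, the piRNA pathway, the acrosome, histone replacement, the sperm tail, germ-cell and somatic isozymes of energy metabolism, GDNF and FGF signalling, dissociation stress, the markers of the sort gate, MHC classes I and II, DNA methylation and cancer-testis antigens. Each was tested in each of the 6 gene comparisons with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 on voom values, adjusted over the lists, and again with an estimated correlation and with fry. The lists overlapped with the markers that named the clusters. Of the 18 genes of undifferentiated spermatogonia 9 were such markers, as were 11 of 34 for synapsis and recombination, 7 of 25 for the acrosome and 5 of 22 for histone replacement.

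Genes are named by a rule fixed before the data were examined. It takes the 10 called genes with the largest rise and the 10 with the largest fall among those with at least 50 CPM in the higher group and all libraries of the groups apart, up to 4 members per list with the smallest adjusted p, and ID4, UTF1, KIT, SYCP3, PRM1 and TNP1. Genes on the Y chromosome, XIST, mitochondrial genes and genes with only a clone name were left out.

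Each script for many genes was tested on simulated data, with 200 genes changed 2-fold or 4-fold at the means and library sizes of the real libraries. Of the genes changed 4-fold, 73.5% were recovered in the design of sorted against steady-state libraries (25980 genes), 55.3% for spermatocyte-enriched against sorted (25959 genes), 38.9% for spermatid-enriched against spermatocyte-enriched (25978 genes), 86.3% within spermatogonia-like (21068 genes), 78% within spermatocyte-like (17476 genes) and 60% within spermatid-like cells (19589 genes). Of those changed 2-fold, the shares were 6.86%, 3.09%, 0.952%, 55.1%, 12.8% and 15% in the same order.

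Alternatives fixed before the data were examined were size factors from DESeq2 1.42.0, library size alone, the DESeq2 Wald test, no filter and a stricter filter on low counts (10 CPM in at least 2 libraries), leaving out each library in turn, only the libraries of the groups compared, the cell filter on or off, predicted doublets removed, resolutions 0.2 and 0.8, and a replicate block. Chosen after the data had been seen were the restrictions to certain clusters, the removal of somatic-like cells and the first naming rule. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.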

Results

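Gene expression was measured cell by cell in adult human testis, where spermatogonia renew themselves and give rise to spermatocytes, which pass through meiosis to become spermatids. The 10 human libraries comprised 3 of sorted spermatogonia, 3 of steady-state spermatogenic cells, 2 enriched for spermatocytes and 2 enriched for spermatids by sedimentation, and a further library mixed human and mouse cells. The spermatogonia libraries held 4082, 3500 and 3522 barcodes with 41042449, 29846453 and 52775479 UMIs. The steady-state libraries held 2272, 2360 and 2502 barcodes with 35898098, 51950501 and 61233946 UMIs. Spermatocyte-enriched replicates 6 and 11 held 2757 and 2127 barcodes with 90288168 and 70561412 UMIs, and spermatid-enriched replicates 6 and 11 held 3086 and 4348 barcodes with 58117192 and 73661183 UMIs. The median mitochondrial share of a barcode's UMIs was 6.76%, 4.84% and 8.30% in sorted spermatogonia replicates 1, 2 and 5 and 0.349%, 0.643% and 5.14% in steady-state replicates 3, 4 and 5. It was 0.792% and 0.595% in the spermatocyte-enriched and 0.479% and 0.0287% in the spermatid-enriched libraries.

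Cells of sorted spermatogonia libraries were nearly all spermatogonia-like, with a share of 99.8% ± 0.282 (SD, n = 3), against 18.1% ± 12.5 in the other 7 libraries. Steady-state libraries held 24.98% ± 15.6 spermatogonia-like, 23.1% ± 6.97 spermatocyte-like, 39.4% ± 20.8 spermatid-like and 2.72% ± 1.81 somatic-like cells (SD, n = 3). Spermatocyte-like cells made up 50.1% ± 11.9 of the spermatocyte-enriched libraries (SD, n = 2) and 12.2% ± 11.4 of the other 8. Spermatid-like cells made up 46.8% ± 16.3 of the spermatid-enriched libraries (SD, n = 2), which also held 10.8% ± 5.14 somatic-like cells, and 20.7% ± 21.5 of the other 8. The spermatocyte-enriched libraries further held 16.6% ± 9.66 spermatogonia-like and 23.5% ± 3.37 spermatid-like cells. A cluster led by MUC12 and SLC51B took no name and held 0% of sorted, 9.81% of steady-state, 7.27% of spermatocyte-enriched and 18.6% of spermatid-enriched cells on average. The share of spermatogonia-like cells was 81.7 percentage points higher in sorted than in all other libraries, which include the sedimentation fractions (exact two-sided permutation p = 0.00833, the smallest that 120 splits allow). For spermatocyte-like cells the difference was 37.9 points (exact two-sided p = 0.0222, the smallest that 45 splits allow), and for spermatid-like cells it was 26.1 points (exact two-sided p = 0.178). There the other libraries include the sorted ones, with 0.00953% spermatocyte-like and 0.0191% spermatid-like cells on average. Relative to the steady-state mean, the 3 shares were 4, 2.17 and 1.19 times as large. Against the steady-state libraries alone, which ranged from 19.2% to 60.8% spermatid-like cells, the spermatid difference was 7.35 points (exact two-sided p = 0.8). It fell to 14.6 points over all other libraries without spermatid-enriched replicate 11 (exact p = 0.667). With clusters at resolution 0.8 and the naming rule first tried, the spermatogonial difference was 50.3 points.

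**Figure D1:**
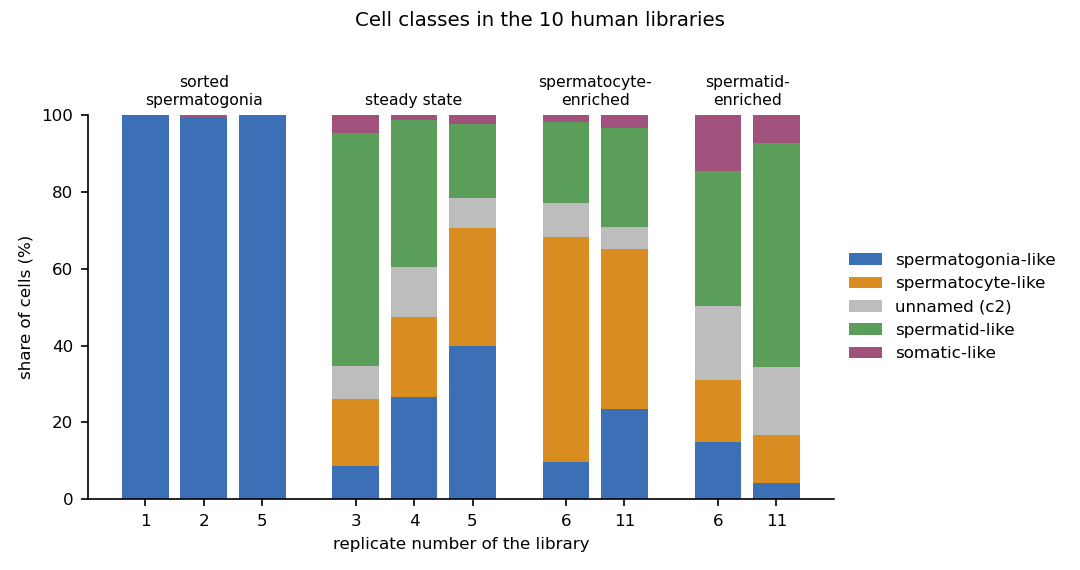
Share of cells (percent) in each class for each human library, grouped by isolation. Sorted spermatogonia libraries were 99.8% spermatogonia-like on average, and the sedimentation libraries held every class.

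Spermatogonia-like cells fell into several clusters that the isolations held in different parts. Of these cells in sorted libraries, 50.1% were in cluster c0, 38.6% in c1, 8.14% in c7 and 2.35% in c9, while in steady-state libraries c9 held 33.8%. Cluster c7 was led by UBE2C, MKI67, CCNA2, RRM2 and TOP2A, genes of dividing cells, and c9 by PNMA5, DHRS2, DMRT1, SSX3 and CLSPN. Of the spermatocyte-like cells, c15 held 33.6% in steady-state and 0.600% in spermatocyte-enriched libraries. In turn c8 held 24.5% of them in spermatocyte-enriched and 0.424% in steady-state libraries, with 68.7% in spermatocyte-enriched replicate 11 and 0.124% in replicate 6. RAD51AP2, MEIOB, TEX101, DMC1 and SPO11 led c15, genes of early prophase in which DNA breaks are made and repaired. Spermatid-like cells were in c11, c13 and c14 for 16.4%, 15.5% and 15.1% in spermatid-enriched libraries, all from replicate 11, and for 0.255%, 0.873% and 0.182% in steady-state libraries. Somatic-like cells of the spermatid-enriched libraries were 86.2% from c12, led by PTGDS, ACTA2, TAGLN, MYL9 and DCN. The marker list that named c12 was that of Leydig cells, while ACTA2, TAGLN and DCN are markers of peritubular and stromal cells. Its cells were therefore not assigned to a single type.

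The first comparison asked what the sort for spermatogonia selected from the tissue. ID4 (ENSG00000172201, chromosome 6, 19837386 to 19840684, GRCh38), a repressor of differentiation in spermatogonial stem cells, rose from 41.7 ± 22.5 CPM in steady-state to 361 ± 44.7 CPM in sorted libraries (SD, n = 3 each). Its log2 fold change was 3.11 (SE 0.531, edgeR adjusted p = 3.52e-04). UTF1 (ENSG00000171794, chromosome 10, 133230274 to 133231558), a chromatin protein of undifferentiated spermatogonia, stood at 428 ± 73.7 CPM in sorted and 52.1 ± 43.0 CPM in steady-state libraries (log2 3.04, SE 0.61, edgeR adjusted p = 1.02e-03). TNP1 (ENSG00000118245, chromosome 2, 216859458 to 216860064), which replaces histones in spermatids, was at 0.861 ± 0.0576 CPM in sorted and 5919 ± 4304 CPM in steady-state libraries (log2 -12.75, SE 0.739, edgeR adjusted p = 8.67e-08). PRM1 (ENSG00000175646, chromosome 16, 11280836 to 11281350), a protamine of the sperm head, was at 6.64 and 25710 CPM, and PRM2 fell by 12.12 on the log2 scale. SYCP3, a rod protein of the synaptonemal complex, was 42.6 CPM in sorted and 182 CPM in steady-state libraries (log2 -2.10). The transcription cofactor ZFPM1 had the largest named rise, 3.97 on the log2 scale (SE 0.643, edgeR adjusted p = 2.43e-04), from 4.48 to 70.5 CPM, and KIT, a receptor of differentiating spermatogonia, rose by 1.88. Besides these, C19orf84, RGS14, CDK17 and PIWIL4 were higher and CCNA1, IZUMO4, ROPN1 and PGK2, genes of meiosis, the acrosome, the tail and spermatid glycolysis, were lower with log2 values of -7.00, -7.63, -10.04 and -9.75. Of 26665 genes tested, edgeR called 19231, 9225 higher and 10006 lower in sorted libraries. With library size alone the median of all genes moved to 0.34 on the log2 scale, from 0.05, so folds are relative to the TMM scaling.

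**Figure D2:**
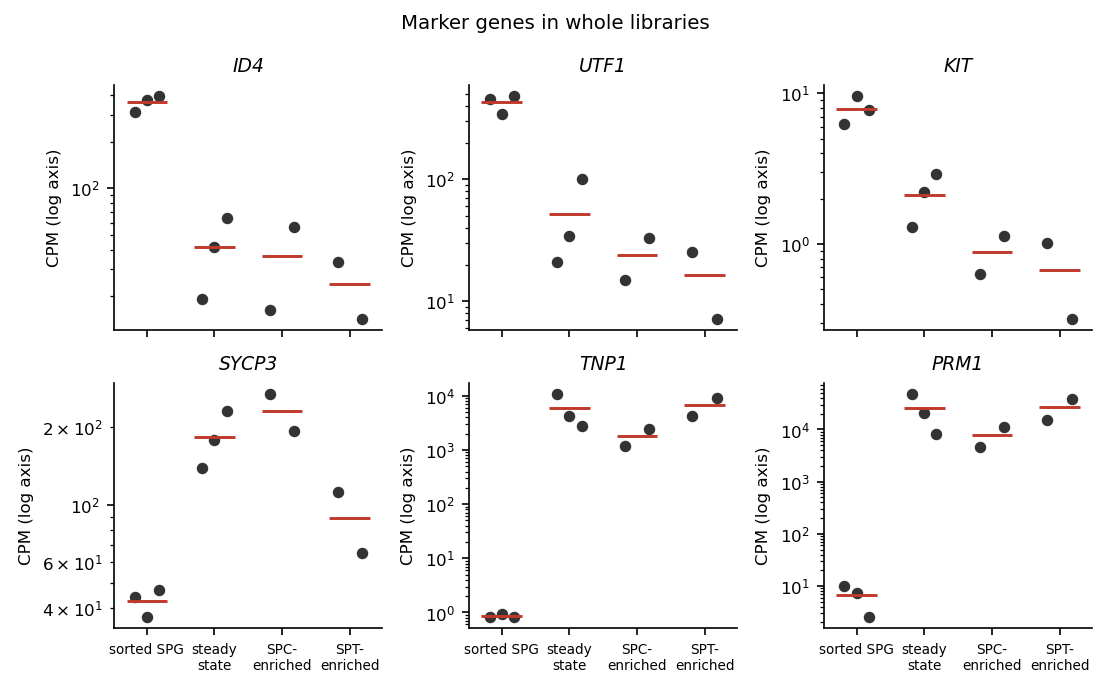
CPM on a log axis of marker genes in each human library, grouped by isolation. ID4 and UTF1 were highest in sorted spermatogonia, where TNP1 and PRM1 were lowest.

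Genes of undifferentiated spermatogonia rose together in sorted libraries, 15 of 17 tested (camera adjusted p = 1.59e-05; adjusted p = 0.387 with an estimated correlation). The DNA methylation list had 8 of 9 higher, among them DNMT3B and TDG (camera adjusted p = 8.45e-03; adjusted p = 0.428 with an estimated correlation). Of 25 cancer-testis antigens, germ-cell genes that tumours also express, 20 were higher, PAGE5 by 2.30 on the log2 scale, and SPANXB1 fell by 5.64 (camera adjusted p = 2.03e-04; adjusted p = 0.428 with an estimated correlation). All 34 sperm tail genes were lower (camera adjusted p = 3.8e-14; adjusted p = 0.16 with an estimated correlation), as were 23 of 24 acrosome genes (4.27e-10; adjusted p = 0.239 with an estimated correlation). Histone replacement had 11 of 17 lower (camera adjusted p = 7.37e-04; adjusted p = 0.143 with an estimated correlation), and the germ-cell isozymes 11 of 15 (2.24e-04; adjusted p = 0.152 with an estimated correlation). Synapsis and recombination had 23 of 31 lower and 4 higher (camera adjusted p = 3.61e-04, and adjusted p = 0.361 with an estimated correlation). Meiotic division had 16 of 23 lower and 1 higher (camera adjusted p = 2.03e-04, and adjusted p = 0.428 with an estimated correlation). The other 8 lists did not pass camera. Differentiating spermatogonia had 7 of 14 higher and 5 lower (camera adjusted p = 0.466). The mitotic cell cycle had 7 of 22 higher and 10 lower (camera adjusted p = 0.467). Somatic isozymes had 10 of 17 higher and 3 lower (camera adjusted p = 0.07). GDNF and FGF signalling had 11 of 18 higher and 4 lower (camera adjusted p = 0.0644). Dissociation stress had 7 of 20 higher and 6 lower (camera adjusted p = 0.468). MHC had 9 of 16 lower and 3 higher (camera adjusted p = 0.325). Among the genes of the sort gate, HLA-B fell by 2.70 and EPCAM rose by 1.74 on the log2 scale, with 4 of 8 higher and 3 lower (camera adjusted p = 0.982). That list's median of -0.08 and mean of -0.22 were below 0 while camera pointed up, and the piRNA pathway, with 6 of 19 higher and 8 lower (camera adjusted p = 0.882), had a median of 0.23 and a mean of -0.14. Adjusted over the list alone, the counts were the same in all 17 lists.

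Spermatocyte-enriched libraries were compared with sorted spermatogonia to ask what separates both ends of that step. PPP3R2 (ENSG00000188386, chromosome 9, 101591615 to 101595021), a testis subunit of calcineurin, stood at 1798 ± 28.7 CPM in spermatocyte-enriched (SD, n = 2) and 0.437 ± 0.0855 CPM in sorted libraries (SD, n = 3), a log2 fold change of 12.00 (SE 0.263, edgeR adjusted p = 7.05e-10). CCNA1 (ENSG00000133101, chromosome 13, 36431520 to 36442882), the cyclin of male meiosis, rose by 7.75 (edgeR adjusted p = 2.77e-09) from 3.29 to 706 CPM. SPATA22, needed for recombination, rose by 5.60, BOLL by 6.94, SYCP3 by 2.43, and the sperm isozyme LDHC by 7.01. The spermatid genes TNP1 and PRM1 rose as well, by 11.05 and 10.21, in libraries that also held spermatid-like cells. Lower were C19orf84 (log2 -5.94), UTF1 (-4.16), FGFR3 (-3.92), ID4 (-3.31), KIT (-3.16), PKM (-2.49) and MAGEA10 (-3.45). Of 26665 genes, edgeR called 10256 higher and 9948 lower in spermatocyte-enriched libraries. With library size alone the median of all genes was -0.62 instead of -0.02.

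Lists that rose in spermatocyte-enriched libraries were led by the sperm tail with 34 of 34 higher (camera adjusted p = 3.16e-13; adjusted p = 0.274 with an estimated correlation) and the acrosome with 23 of 24 (4.34e-09; adjusted p = 0.296 with an estimated correlation). Meiotic division had 17 of 23 higher and 2 lower (camera adjusted p = 3.83e-05, and adjusted p = 0.346 with an estimated correlation). Synapsis and recombination had 19 of 31 higher and 7 lower (camera adjusted p = 0.0161, and adjusted p = 0.35 with an estimated correlation). All but 1 of the 15 germ-cell isozymes rose (camera adjusted p = 6.76e-05; adjusted p = 0.274 with an estimated correlation), as did 12 of 17 genes of histone replacement (3.96e-03; adjusted p = 0.293 with an estimated correlation). Of the somatic isozymes 11 of 17 fell, 12 adjusted over the list alone, and 4 rose (camera adjusted p = 0.0442, and adjusted p = 0.35 with an estimated correlation). Lower were also 15 of 17 genes of undifferentiated spermatogonia (camera adjusted p = 3.83e-05; adjusted p = 0.35 with an estimated correlation), 8 of 9 of DNA methylation (6.65e-03; adjusted p = 0.35 with an estimated correlation) and 21 of 25 cancer-testis antigens (1.85e-05; adjusted p = 0.35 with an estimated correlation). For the sort gate the median was 0.30, the mean -0.05 and the test pointed down. Counts adjusted over the list alone differed by at most 1 gene.

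Spermatid-enriched and spermatocyte-enriched libraries came from the same kind of gradient and were compared to see what the fractions separate. ACTA2 (ENSG00000107796, chromosome 10, 88935074 to 88991339), the actin of smooth muscle and of the cells around the tubule, was at 204 ± 102 CPM in spermatid-enriched and 12.8 ± 3.14 CPM in spermatocyte-enriched libraries (SD, n = 2 each; log2 4.00, SE 0.593, edgeR adjusted p = 0.0262). The contractile genes MYH11, MYL9, TAGLN, TPM2 and MYLK rose by 3.46, 3.17, 3.05, 2.87 and 2.84, and TIMP1 and FHL2 by 3.20 and 3.56. CKS2 (ENSG00000123975, chromosome 9, 89311198 to 89316703), a partner of the kinase CDK1 in division, fell from 858 ± 23.4 to 165 ± 59.1 CPM (log2 -2.37, SE 0.363, edgeR adjusted p = 0.0262). CETN3, PIWIL1, HENMT1, SLC25A31, PSMC3IP, RNF8, CDK1 and BIRC5 were lower too, by log2 values of -2.55, -1.78, -1.85, -1.99, -1.50, -1.45, -1.20 and -1.16. The spermatid genes TNP1 (log2 1.89, edgeR adjusted p = 0.137) and PRM1 (log2 1.77, edgeR adjusted p = 0.294) did not pass, nor did SYCP3 (log2 -1.38, edgeR adjusted p = 0.0659). In spermatid-enriched replicates 6 and 11 TNP1 was at 4265 and 9222 CPM and PRM1 at 15220 and 38400 CPM, and in spermatocyte-enriched replicates 6 and 11 they were at 1208 and 2435 and at 4530 and 11180 CPM, so the groups did not overlap for either gene. Of 26665 genes edgeR called 270, 125 higher and 145 lower.

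The count moved with single libraries and with the scaling. With edgeR, 0 genes were called without spermatocyte-enriched replicate 6 (2099 at unadjusted p under 0.05), 0 without spermatocyte-enriched replicate 11 (5476), 24 without spermatid-enriched replicate 6 and 146 without spermatid-enriched replicate 11, of which 137 were higher. Without somatic-like cells edgeR called 0 genes (3402 at unadjusted p under 0.05), with a smallest adjusted p of 0.0585. DESeq2, run on all cells, called 1978, of which 119 were among the 125 higher and 145 among the 145 lower ones. With edgeR on the 4 libraries of these groups alone 69 genes were called, 54 of them higher. Of the called genes, 46.3% were higher, against 89.7% of 68 with library size alone, where the median of all genes was 0.28 instead of 0.11, and 35.5% of 470 with DESeq2 size factors. Genes of meiotic division lay lower, with 2 of 23 called and 9 adjusted over the list alone (camera adjusted p = 2.14e-09; adjusted p = 0.182 with an estimated correlation). The piRNA pathway had 2 lower, 5 adjusted over the list alone (camera adjusted p = 5.06e-06; adjusted p = 0.137 with an estimated correlation), and synapsis and recombination 1, or 6 adjusted over the list alone (3.21e-04; adjusted p = 0.265 with an estimated correlation). The germ-cell isozymes had 1 lower, and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.73e-03; adjusted p = 0.254 with an estimated correlation). The mitotic cell cycle had 2 lower, and 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0139; adjusted p = 0.409 with an estimated correlation). Dissociation stress lay higher, with 1 gene called, ATF3, and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.06e-07; adjusted p = 0.254 with an estimated correlation). Without somatic-like cells ATF3 was at 0.96 on the log2 scale instead of 2.36 and no longer passed. GDNF and FGF signalling had 0 genes called by edgeR and 3 higher adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.409 with an estimated correlation). Median, mean and test differed in sign for undifferentiated spermatogonia (-0.14, -0.07 and up), the sperm tail (0.10, -1.8e-04 and down) and the sort gate (-0.03, 0.24 and up).

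Spermatogonia-like cells of sorted and of steady-state libraries were compared to ask whether the sort takes a part of them. NANOS2 (ENSG00000188425, chromosome 19, 45913214 to 45914870), an RNA-binding protein that holds spermatogonia undifferentiated, stood at 61.9 ± 6.58 CPM in sorted and 21.7 ± 8.23 CPM in steady-state cells (SD, n = 3 each; log2 1.42, SE 0.207, edgeR adjusted p = 3.51e-04). ID4 rose by 0.82 (SE 0.133, edgeR adjusted p = 8.07e-04), UTF1 by 0.76, ZFPM1 by 2.01 and the methyl-CpG reader MBD2 by 1.65. Genes of the turn to differentiation and meiosis were lower, REC8 by -2.24, STRA8 by -2.97, DNMT1 by -1.74, SYCE2 by -2.05 and SYCP3 by -1.69 on the log2 scale. The largest falls were of spermatid genes. TNP1 was at 1.03 ± 0.0421 CPM in sorted and 559 ± 42.1 CPM in steady-state spermatogonia-like cells (log2 -9.07, SE 0.177, edgeR adjusted p = 2.38e-11), and PRM2 and PRM1 changed by -8.73 and -8.41. Somatic-like cells of steady-state replicates 3 and 5 also held TNP1, PRM1 and PRM2, together at 8139 and 15080 CPM. In spermatogonia-like cells of these libraries they were at 7495 and 3289 CPM. These falls therefore do not tell expression in spermatogonia from RNA free in the steady-state suspensions. TEX19 (ENSG00000182459, chromosome 17, 82359247 to 82363776) changed by -8.36, ACTL7A of the acrosome by -7.58 and PGK2 by -5.45. KIT did not pass (log2 -0.44, edgeR adjusted p = 0.161).

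Of 21526 genes in spermatogonia-like cells, edgeR called 2094 higher and 3344 lower in sorted libraries, 5438 in all. The count was 3301 without steady-state replicate 4. It was 2117 at resolution 0.8, with 360 higher, 1366 without cluster c9, with 64 higher, and 1355 with clusters c0 and c1 alone, with 76 higher. Without c9, NANOS2 was still higher by 0.85 and TNP1 lower by -9.08 with edgeR adjusted p under the threshold, while ZFPM1 (1.55), ID4 (0.21), UTF1 (0.18), REC8 (-0.60), SYCP3 (-0.29), DNMT1 (-0.07) and STRA8 (-0.0096) no longer passed. STRA8 was at 0.086 with c0 and c1 alone. With library size alone 26.1% of the calls were higher, against 38.5%. Undifferentiated spermatogonia genes had 7 of 17 higher, 9 adjusted over the list alone (camera adjusted p = 1e-04; adjusted p = 0.138 with an estimated correlation). Differentiating spermatogonia had 6 of 14 lower, the same adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.138 with an estimated correlation), the mitotic cell cycle 12 of 22 lower, the same adjusted over the list alone (9.9e-06; adjusted p = 0.161 with an estimated correlation), and synapsis and recombination 16 of 31, 18 adjusted over the list alone (1.38e-06; adjusted p = 0.0611 with an estimated correlation). Meiotic division had 8 of 23 lower, 8 adjusted over the list alone (camera adjusted p = 5.88e-04; adjusted p = 0.161 with an estimated correlation), the acrosome 20 of 23, 22 adjusted over the list alone (4.12e-21; adjusted p = 0.0823 with an estimated correlation), histone replacement 11 of 17, 11 adjusted over the list alone (9.75e-09; adjusted p = 0.0926 with an estimated correlation) and the sperm tail 23 of 34, 23 adjusted over the list alone (2.53e-14; adjusted p = 0.0611 with an estimated correlation). The germ-cell isozymes had 7 of 15 lower, 8 adjusted over the list alone (camera adjusted p = 1.33e-03; adjusted p = 0.181 with an estimated correlation), and GDNF and FGF signalling, which keeps the stem cell pool, 3 of 16 higher, 5 adjusted over the list alone (0.0412; adjusted p = 0.178 with an estimated correlation). Median, mean and test differed in sign for the somatic isozymes (0.14, -0.04 and up), dissociation stress (-0.05, -0.04 and up) and the cancer-testis antigens (4.8e-04, -0.09 and up).

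**Figure D3:**
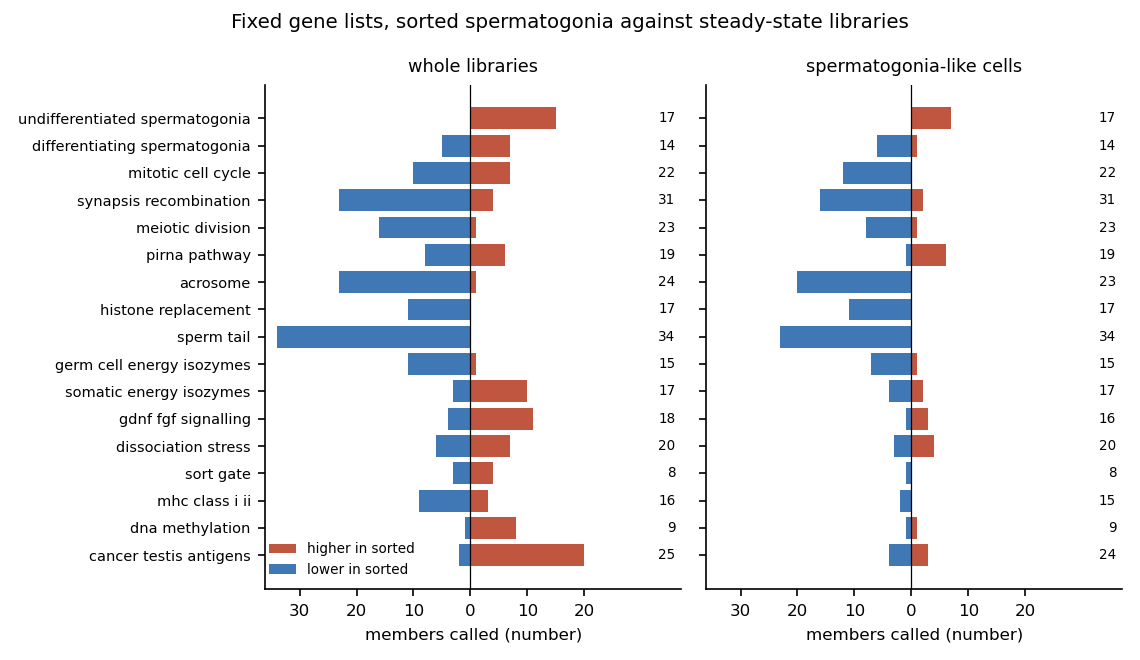
Numbers of members of the fixed gene lists called higher or lower, sorted against steady-state, over whole libraries and within spermatogonia-like cells. Undifferentiated spermatogonia genes were called higher more often than lower in both, and genes of the acrosome and the sperm tail lower more often than higher. RNA free in the suspensions was not removed from these counts.

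Spermatocyte-like cells of spermatocyte-enriched and of steady-state libraries were compared to ask whether sedimentation takes a part of them. RAD51AP2 (ENSG00000214842, chromosome 2, 17510584 to 17518439), a gene of early meiotic prophase, was at 2.05 ± 0.978 CPM in enriched (SD, n = 2) and 94.8 ± 5.13 CPM in steady-state cells (SD, n = 3; log2 -5.56, SE 0.335, edgeR adjusted p = 1.65e-04). The recombinase DMC1 (ENSG00000100206, chromosome 22, 38518949 to 38570286) changed by -4.72 (SE 0.262, edgeR adjusted p = 1.65e-04). MEIOB (ENSG00000162039, chromosome 16, 1833987 to 1884294), which binds single-stranded DNA at breaks, changed by -3.71, SPO11, which makes the breaks, by -3.73, TEX19 by -5.47 and SYCP1 by -1.83. The X-linked cancer-testis antigens SSX3, PAGE1 and VCX changed by -5.86, -4.60 and -3.87, and the spermatid genes TNP1 and PRM2 by -2.35 and -2.74. Higher were PRPH (1.58), SOHLH2 (1.35), TBPL1 (0.85), a relative of the TATA-binding protein in late spermatocytes, LDHC (0.76) and the antisense gene LIFR-AS1 (2.31). SYCP3 did not pass (log2 -0.20, edgeR adjusted p = 0.328).

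Of 18058 genes in spermatocyte-like cells, edgeR called 1890 higher and 3106 lower in enriched libraries, 4996 in all. Without cluster c15 the count was 22, with 6 higher and 16 lower, among the latter TEX19, TNP1 and PRM2 at -4.30, -2.31 and -2.49. RAD51AP2 (-2.59), DMC1 (-2.52), MEIOB (-2.02), SPO11 (-1.59) and SSX3 (-3.11) stayed lower there and did not pass, nor did PRPH (1.25), SOHLH2 (1.12), TBPL1 (0.53) and LDHC (0.43), and TBPL1 turned to -0.13 with clusters c4 and c6 alone. The count was 3075 without steady-state replicate 5, 2963 without spermatocyte-enriched replicate 6 and 2297 without spermatocyte-enriched replicate 11, and 3293 at resolution 0.2. Scaling moved the split of the calls, with 37.8% higher after TMM, 6.75% with library size alone, where the median of all genes was -0.51 instead of -0.09, and 48.7% with DESeq2. Cancer-testis antigens had 20 of 21 lower, 21 adjusted over the list alone (camera adjusted p = 3.64e-12; adjusted p = 0.285 with an estimated correlation). Synapsis and recombination had 14 of 31 lower and 3 higher, 16 and 3 adjusted over the list alone (camera adjusted p = 8.25e-03; adjusted p = 0.285 with an estimated correlation), and histone replacement 10 of 17 lower, 12 adjusted over the list alone (8.85e-03; adjusted p = 0.443 with an estimated correlation). The germ-cell isozymes had 7 of 15 higher, 8 adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.477 with an estimated correlation). Meiotic division had 5 of 23 higher, 5 adjusted over the list alone (camera adjusted p = 8.25e-03; adjusted p = 0.477 with an estimated correlation) and did not pass with library size alone (0.0613). The mitotic cell cycle (median 0.10, mean -0.39, test up) and dissociation stress (-0.30, -0.31, up) differed in sign.

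Spermatid-like cells of spermatid-enriched and of steady-state libraries were compared with the same question for spermatids. The comparison ran across the differing clusters c11, c13 and c14, which followed number 11 in both kinds of fraction. TNP1 stood at 11260 ± 2418 CPM in enriched (SD, n = 2) and 12370 ± 5750 CPM in steady-state cells (SD, n = 3), a log2 fold change of -0.14 (edgeR adjusted p = 0.997). The early response gene FOS rose by 2.58 without passing (edgeR adjusted p = 0.983). Of 20062 genes edgeR called 1, lower in enriched cells, and 993 had an unadjusted p under 0.05. That gene was TBC1D3D (ENSG00000274419, chromosome 17, 38003976 to 38014902), at 0.231 against 22.7 CPM (log2 -6.52, SE 0.572, edgeR adjusted p = 0.0283). It is 1 of a family of near-identical copies among which counts cannot be told apart, and it was named after its values were seen. The edgeR count was 0 without steady-state replicate 3 (1055 at unadjusted p under 0.05) and 0 without steady-state replicate 4 (953), 11 without spermatid-enriched replicate 6 and 3 without spermatid-enriched replicate 11. DESeq2 on the same cells called 54, and edgeR without a filter on low counts 35. Dissociation stress genes lay higher, with 0 called by edgeR over all genes and 2 higher adjusted over the list alone (camera adjusted p = 1.78e-04; adjusted p = 0.638 with an estimated correlation). Spermatid-enriched replicate 6, with the largest somatic-like share of the human libraries (14.5%), stood above replicate 11 for FOS (18.4 and 6.604 CPM), IER2 (11.9 and 2.69 CPM) and ZFP36 (5.41 and 1.12 CPM). Cancer-testis antigens lay lower, with 0 called over all genes and 4 adjusted over the list alone (camera adjusted p = 6.11e-08; adjusted p = 0.638 with an estimated correlation). Their levels were low, with SSX3 at 1.22 CPM in steady-state spermatid-like and 101 CPM in steady-state spermatogonia-like cells. Synapsis and recombination (camera adjusted p = 0.0216; adjusted p = 0.638 with an estimated correlation) and the mitotic cell cycle (0.0438; adjusted p = 0.727 with an estimated correlation) also passed, the latter not with library size alone (0.0652). The piRNA pathway had a median of 0.06 and a mean of -0.0062.

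The X chromosome is silenced in male meiosis, and its share of UMIs was followed across the classes. Spermatogonia-like cells drew 2.50% ± 0.129 of their UMIs from X-linked genes (SD, n = 7 libraries), spermatocyte-like cells 0.221% ± 0.167 and spermatid-like cells 0.797% ± 0.212. Within libraries the mean log2 ratio to spermatogonia-like cells was -3.93 ± 1.23 for spermatocyte-like cells, lower in 7 of 7 libraries (exact two-sided sign-flip p = 0.0156, the smallest possible). For spermatid-like cells it was -1.70 ± 0.48, lower in 7 of 7 (exact two-sided p = 0.0156). Both tests take the 7 libraries as independent, although the 4 sedimentation libraries carry only numbers 6 and 11. In the 3 steady-state libraries alone the ratios were -2.71 and -1.59 (exact two-sided p = 0.25 each, the smallest that 3 libraries allow). The share differed between clusters of spermatocyte-like cells, with a median of 2.43% in c15, 0.114% in c4, 0.0936% in c6 and 0.0457% in c8. Among spermatogonia-like cells it was 2.50% in c0, 2.52% in c1 and 2.77% in c9.

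**Figure D4:**
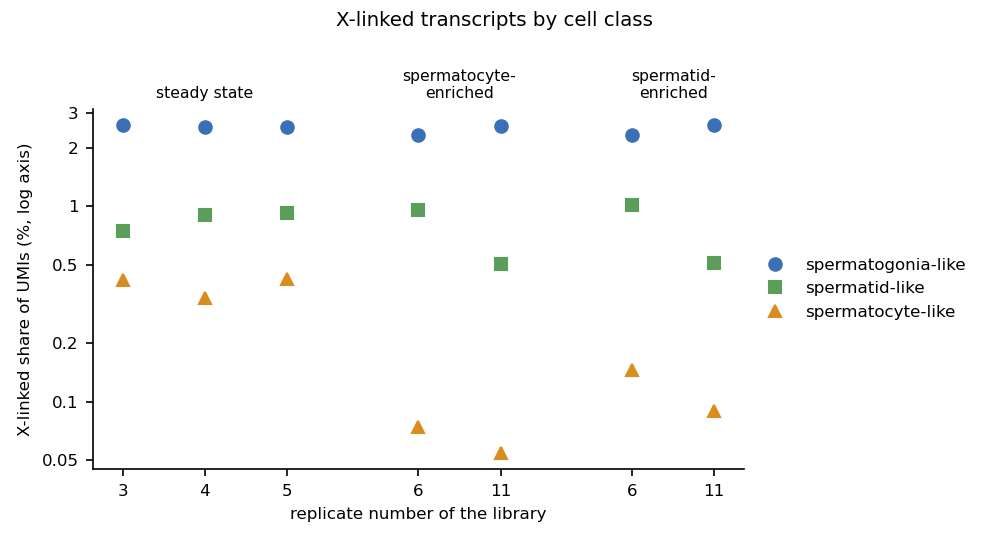
Share of UMIs from X-linked genes (percent, log axis) in spermatogonia-like, spermatocyte-like and spermatid-like cells of the 7 libraries that held all of them. Spermatocyte-like cells were lowest in each library.

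The human and mouse mixture was made to measure multiplets, barcodes that hold more than 1 cell. Of 2171 barcodes called in either genome, 11 were called in both, 0.507% (exact binomial 95% interval 0.253% to 0.905%). With at least 10% of the UMIs from each genome required, 8 barcodes passed, 0.369% (0.159% to 0.725%). The mixture held 921 barcodes called human and 1261 called mouse, so a multiplet mixes the species in an expected 48.8% of cases, and the rate scaled to all multiplets was 1.04% (0.519% to 1.86%). This is 1 library without a replicate.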

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

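The tests of the X-linked share with cluster c15 left out were chosen only after the result was seen, and the others here were not.

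The fall of the X-linked share from spermatogonia-like to spermatocyte-like cells differed between isolations. Its mean log2 ratio was -2.71 ± 0.17 in steady-state (SD, n = 3) and -4.85 ± 0.64 in the sedimentation libraries (SD, n = 4), a difference of 2.14 (exact two-sided permutation p = 0.0286, the smallest that 35 splits allow). That p takes the 4 sedimentation libraries as independent, although they carry only numbers 6 and 11. Cluster c15, early spermatocyte-like cells with a median X-linked share of 2.43%, was 33.6% of the spermatocyte-like cells in steady-state, 0.600% in spermatocyte-enriched and 4.21% in spermatid-enriched libraries. Without c15 the ratios were -4.33 and -5.12, which differed by 0.79 (exact two-sided p = 0.114). For spermatid-like cells the isolations differed by 0.20 (exact two-sided p = 0.543). That mean hides a split by number, with log2 ratios of -1.27 and -1.19 in the number 6 libraries, -2.33 and -2.35 in the number 11 libraries and -1.46 to -1.80 in steady-state libraries.

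Spermatid genes were also read in the mixture, a library that served only to count multiplets and that no gene comparison used. PRM1 was at 38060 CPM of the human UMIs (Poisson 95% interval 37940 to 38170), where the steady-state libraries ranged from 8963 to 44690 and the spermatid-enriched ones from 14940 to 32770. TNP2 was at 68.2 CPM (63.5 to 73.1), against 31.9 to 119 in steady-state and 19.9 to 51.9 in spermatid-enriched libraries. The mouse transition protein Tnp2 was at 9458 CPM of the mouse UMIs (9432 to 9483). There was 1 such library with no replicate, the intervals cover counting error only, and whether the human cells of the mixture came from a group listed here is not given in the sources used here. No explanation was tested for these levels.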

How the results depend on the processing

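Tests with restricted clusters, with somatic-like cells removed or with the first naming rule were chosen only after the results were seen, and the other alternatives before the data were examined. Unless a construction is named, the cause was not tested.

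Genes named for sorted against steady-state libraries kept direction and side of the threshold in 1167 of 1168 pairs of gene and alternative, and those for spermatocyte-enriched against sorted libraries in 1126 of 1126. For spermatid-enriched against spermatocyte-enriched libraries it was 203 of 364, with 160 weaker. Within spermatogonia-like cells it was 1155 of 1308 and within spermatocyte-like cells 933 of 1179.

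The stricter filter, which tested fewer genes, gave 10504, 10563 and 110 genes for the 3 comparisons of whole libraries in the order of the report, 3417 in spermatogonia-like and 1738 in spermatocyte-like cells. Leaving out 1 library gave 17294 to 19065, 17749 to 18792 and 0 to 146 genes, and within classes 3301 to 5743, 2297 to 4009 and 0 to 11. Where that left 1 library in a group, it was assumed to vary like the others. For spermatid-enriched against spermatocyte-enriched libraries the count was 470 with DESeq2 size factors, 68 with library size alone, 1978 with the DESeq2 Wald test, 69 with only those 4 libraries, and 0 with edgeR without somatic-like cells (3402 at unadjusted p under 0.05), where TCEAL4 turned to -0.11. With replicate number as a block that pairs these 4 libraries, 3970 genes were called, 123 and 143 of them among the 125 higher and 145 lower ones, and the differences between numbers 6 and 11 correlated across genes at r = 0.485. Genes are not independent replicates. No paired analysis was possible for the other comparisons because their groups share at most 1 number.

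Within spermatogonia-like cells the count was 2117 at resolution 0.8, 3116 there with the first naming rule, 1366 without c9 and 1355 with c0 and c1 alone. Direction turned for RRM2 (0.47 without c9, 0.053 with c0 and c1), SSX3 (0.26, 0.27), PAGE1 (0.12, 0.14) and STRA8 (0.086 with c0 and c1). HLA-F turned to 0.11 without a cell filter, 0.17 at resolution 0.8, 0.15 there with the first naming rule, 0.11 without c9 and 0.12 with c0 and c1. Within spermatocyte-like cells the count was 3293 at resolution 0.2, 22 without c15 and 5 with c4 and c6 alone. Without c15 DUSP1 turned to 0.13 and EPCAM to 0.31. With c4 and c6 alone CD58 was at -0.036, TBPL1 at -0.13, ASZ1 at 0.41, DNAJB1 at -0.021, DUSP1 at 0.92 and EPCAM at 0.50. Within spermatid-like cells the count was 54 with DESeq2, 35 without a filter on low counts and 0 by edgeR with c3, c5 and c10 alone (919 at unadjusted p under 0.05).

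Against steady-state libraries alone the share differences were 74.8, 27.1 and 7.35 points for spermatogonia-like, spermatocyte-like and spermatid-like cells, where an exact test cannot go below p = 0.1. Leaving out 1 enriched library gave 81.6 to 81.8, 29.5 to 46.3 and 14.6 to 37.7 points for the 3 classes. With steady-state libraries alone the X-linked log2 ratios were -2.71 and -1.59, where the exact test of 3 libraries cannot go below p = 0.25. The multiplet rate was 1.04% when scaled by construction to all multiplets. With an estimated correlation 0 lists passed camera in any of the 6 comparisons, and fry, which does not compare a list with other genes, passed 14, 14, 5, 10, 7 and 0.

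Depth limits genes near the floor of 0.0332 to 0.101 CPM. In simulated whole libraries 2-fold changes were recovered for 6.86%, 3.09% and 0.952% of the changed genes in the 3 comparisons. The simulation changed 200 genes, far fewer than the first 2 comparisons called, and the adjustment of p is milder with more calls. The first 2 shares therefore do not carry over to those comparisons. Small differences between spermatid-enriched and spermatocyte-enriched libraries were mostly not detectable with edgeR and no replicate block. The design with that block, which called more genes, was not simulated.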

Other observations

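The tests with somatic-like cells removed and those restricted by cluster were chosen only after the result was seen.

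In the mixture the mouse cells carried Prm1 at 20610 CPM and Ldhc at 6161 CPM, against 1640 CPM for human LDHC. SYCP3 and Sycp3 were at 147 and 140 CPM, and the stromal gene DCN and its mouse counterpart Dcn at 21.1 and 0.302 CPM.

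The lower genes of sorted spermatogonia-like cells were weighed against differentiating cells and free RNA. With c0 and c1 alone, 37.6% of the 3344 genes (1257) were still called. The median log2 value of the lower genes went from -1.04 to -0.58 with a median SE of 0.204 and 0.234. Calls ended as folds shrank and, in part, as spread grew. A larger part of differentiating spermatogonia (c9) in steady-state libraries may account for part of these falls. Most of the median log2 value stayed, so the ended calls do not measure how large a part. Of the 1257 still called, 90.5% had at least 10 times the CPM in steady-state spermatocyte-like or spermatid-like cells. So had 46.4% of all 3344, which falls between the bounds set for free RNA, and 11.6% of all genes tested. Those bounds were set for all 3344 genes, and the 90.5% lies above them. The CPM of TNP1, PRM1 and PRM2 in steady-state spermatogonia-like cells was 0.448 times that in somatic-like cells of the same libraries, as a geometric mean. This mean and replicate 3 (0.921) lay within the bounds set for RNA free in the suspension. Replicate 5 (0.218) lay below them, with 3289 CPM in spermatogonia-like and 15080 CPM in somatic-like cells. The bound set against free RNA was a ratio over 10, which neither replicate approached. A sort-related difference in the cells themselves stays open as untested.

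The higher genes of spermatid-enriched over spermatocyte-enriched libraries were weighed against the make-up of the fractions. Without somatic-like cells their median log2 value was 1.04 instead of 3.19, 32.7% of it, with a median SE of 0.612 and 0.55, and calls ended because the folds fell. Of the 125 genes, 124 had at least 2 times the CPM in somatic-like than in spermatocyte-like and spermatid-like cells, as somatic-like cells as their source would give. ACTA2, at 204 CPM, is a peritubular marker, while c12, with most of these somatic-like cells, was named from the Leydig list. Which somatic type was the source was not tested. By the same CPM per class, which is no separate evidence, 0% of the 125 genes had at least 2 times the CPM in spermatid-like than in both other classes. That argues against spermatid-like cells as the source of these 125 genes, not against a larger part of such cells. Their share was 46.8% in spermatid-enriched and 23.5% in spermatocyte-enriched libraries. A 2-fold change was recovered for only 0.952% of genes simulated in this design, and TNP1 and PRM1 lay higher without passing. The 145 lower genes moved only from -1.65 to -1.55 at an SE of 0.292, and their calls ended at a smallest adjusted p of 0.0585 by edgeR, while other differences between the fractions stay open as untested.

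The lower genes of spermatocyte-like cells in spermatocyte-enriched libraries were weighed likewise. Without c15 0.515% of the 3106 genes (16) were still called, with a median log2 value of -1.02 instead of -1.68 and a median SE of 0.413 and 0.363. Early prophase cells kept in steady-state but not in enriched libraries may account for part of these falls. Most of the median log2 value stayed without c15, so the ended calls do not measure how large a part. Part of the loss of calls is spread that grew. Free RNA cannot be told apart from early prophase cells by these values. Of the genes, 32.5% had at least 10 times the CPM in steady-state spermatogonia-like or spermatid-like cells, between the bounds set. The share was 20.2% among all genes tested. Cluster c8, which followed number 11 (68.7% of these cells in spermatocyte-enriched and 90.9% in spermatid-enriched replicate 11, 0.124% in spermatocyte-enriched replicate 6), and a difference between spermatocytes of equal stage stay open.

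Both comparisons of 3 sorted with 3 steady-state libraries allow only 10 splits, too few for a share under 0.05. In whole libraries the real split called 19231 genes and the highest of the others 0, and in spermatogonia-like cells 5438 and 1, so 1 of 10 splits reached the real count in each. Every other split puts sorted and steady-state libraries into the same group, which widens the spread in the fit. Low counts in those splits were thus built in, and the contrast decides nothing.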
